A study of Oryza sativa Japonica Group with 24 samples.

How the data were processed

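Total RNA from shoots of rice seedlings was hybridised to one-colour Affymetrix rice arrays as biotin-labelled cRNA, per the labels' protocols. The deposited table holds 1 linear intensity per probe set and array, the authors' processed values. Per the labels only the array type and the labelling are named, and the software, background correction and scaling behind the intensities are not given in the sources used here. From the values, the intensities reach down to 1, and array medians differ (63.1 to 76.1), so the 24 columns had not been brought to a common distribution. Each column was assigned to its sample through the labels, which give the inoculum (live or dead bacteria), the day after inoculation (1, 2, 5 or 8) and the biological repeat (1 to 3). The number of value columns belonging to no sample was 0.

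Values below a floor of 16 were raised to it and log2 was taken, with no further normalization. Of 57381 probe sets, 187 control and reporter probe sets were left out. Those whose mean log2 value over all arrays was above the 40th percentile of the remaining 57194 were tested, 34316 in all. Names came from the platform annotation through the gene identifier, looked up in a gene table of the assembly GCF_034140825.1, which was used for names only; no coordinates are given. In the annotation 22436 probe sets had 1 gene, 95 several and 34663 none, and all 17905 genes so listed were found in the gene table. No gene was named from a probe set with several genes. Of 15743 tested genes, 2209 carry a name other than a locus or clone number. A gene with several probe sets was represented by the one with the highest mean over the arrays. Probe sets that match several transcripts may read related genes together; they were kept, and their omission was an alternative.

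Tests used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on 8 group means over the 24 arrays, which leaves 16 residual degrees of freedom, with Benjamini-Hochberg adjustment at 0.05 over the tested probe sets of each contrast. The contrasts were live against dead bacteria on each day, their mean over the 4 days, the 6 differences between days with a moderated F test on 3 degrees of freedom, and the change between days in the control. All p values are two-sided, except those of Fisher's exact test, which are one-sided for more sharing than independent lists give. Standard errors are limma's moderated ones. Overlaps of called probe sets between days were tested with Fisher's exact test beside the overlap of independent lists. The live against dead differences of different days share no arrays, but they share the spread estimated for each probe set over the 24 arrays. A probe set with a small spread can thus be called on several days more often than independent lists give.

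Gene lists were compared with other genes by limma's camera with a preset inter-gene correlation of 0.01 and 1 probe set per gene, for lists with at least 5 measured genes. It was adjusted over the 32 lists and 4 days together (128 tests) and, for the control from day 1 to day 8, over the 32 lists. No list passed with the correlation estimated from the data, in the live against dead comparisons or in the control. The 35 lists had been planned by gene description, but the tables held names without descriptions, so each was written again by gene name before any difference between groups was looked at. The tested lists were photosystems, carbon fixation, chlorophyll synthesis, cytosolic ribosomal proteins, cell cycle, DNA replication, histones, expansins, xyloglucan and beta-glucan remodelling, cellulose synthesis, phenylpropanoid and lignin synthesis, pathogenesis-related proteins, diterpenoid phytoalexins, WRKY factors, jasmonate, auxin, gibberellin, cytokinin, ethylene, brassinosteroid, abscisic acid, nitrogen, phosphate, iron, heat shock, glutathione S-transferases, clock, sugar and starch, calcium and MAP kinases, symbiosis signalling, and markers of seed and of root. Lists for flavonoid synthesis (2 members) and class III peroxidases (4) were too small, and none could be formed for plastid ribosomal proteins.

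The genes named were set by a rule. It took, per day, the 8 largest rises and 8 largest falls among named genes past the threshold whose live and dead arrays do not overlap. It also took up to 3 members per list with the smallest p, or 1 member with values only where none passed. Added to these were the 10 genes called in the same direction on most days and the 6 genes with the smallest p for a difference between days. For the control from day 1 to day 8 it took 6 rises, 6 falls and 2 members per list. Where nothing passed, the 3 smallest p in each direction are given as values. The rule asked for an informative description, which was read as a name other than a locus or clone number. The contrasts of the main fit, the thresholds and the naming rule were fixed before the data were examined. Tests and alternatives chosen later are named where they are given. SWEET11 and OsTDL1B in the comparison between days were added after their values were seen.

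Replicate numbers are shared between inocula. On day 1 the arrays of the same number deviated from their group means together (r across probe sets 0.132, 0.107 and 0.109, all above 0.1), so on that day the numbers pair the samples by this check from the data. With the number as a block the day 1 count stayed at 0. The main fit of every day has no block, since the labels do not say what a number stands for. Each sample is a biological repeat per the labels.

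Alternatives were no filter and a filter at the 60th percentile, quantile normalization, centring on array medians, no trend and array weights. Further ones were the replicate number as a block within days or over all days, omission of probe sets that match several transcripts, a floor of 64, log2 of the value plus 16, only the arrays of the 2 groups compared, and omission of each array in turn. For lists they were an estimated correlation and fry. Omission of arrays whose deviation exceeds 1.5 times the median, and centring for the lists, were chosen after the data had been seen. The fit was tested on simulated data for all arrays with 34316 probe sets, 200 of them changed in live day 2. Noise was drawn independently for each probe set, with the same spread in every group. Correlation between genes is therefore not covered, and the false calls and list p values hold only without it. The fit recovered 26 of 50 changes of 0.5 on the log2 scale (52%) and all 50 at each of 1, 1.5 and 2. It made 184 calls in all, of which 8 were false. A list of 20 genes shifted by 0.3 had a camera p of 6.81e-19 and an unshifted one 0.676.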

Results

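Gene expression was measured in shoots of rice seedlings (Oryza sativa, Japonica group) after bacteria had been given to their roots. The bacterium was Sinorhizobium meliloti (S. meliloti1021), a nitrogen-fixing symbiont of alfalfa that forms no nodules on rice. Seedlings grew under sterile conditions in glass bottles and received live cells or, as the control, dead cells of the same strain. Shoots were taken 1, 2, 5 and 8 days later, with 3 biological repeats per inoculum and day, which gave 8 groups and 24 one-colour Affymetrix arrays. Each RNA sample pooled 5 seedlings. The median intensity per array lay between 63.1 and 76.1, and 8.65 to 10.9% of the rice probe sets of an array were below the floor of 16. Arrays correlated with the others of their group at a mean r between 0.981 and 0.995 across probe sets, and replicate 3 of live day 2 lay farthest from its group mean, at 1.72 times the median deviation of the 24 arrays. The number of arrays limits the precision of every value. Differences are given as log2 of live over dead, from 3 arrays per group, and values per group are mean log2 intensity ± SD. The standard error beside a difference is moderated and rests on 1 spread per probe set, pooled over the 8 groups. It is therefore the same on every day for a probe set and does not measure the spread of the arrays compared.

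The first comparison asks whether live bacteria at the roots had altered the shoot 1 day after inoculation. No single gene passed the test on that day, although array weights gave 1481 calls. As lists, chlorophyll synthesis genes and expansins stood slightly higher than other genes in seedlings given live bacteria, but not with an estimated correlation (adjusted p = 0.745). Among genes that carry a name, those nearest to the threshold were CAT-B, a catalase, and YSL12, a metal transporter of the yellow stripe-like family. CAT-B (LOC4342124) was at 11.40 ± 0.07 with live and 11.61 ± 0.01 with dead bacteria, a log2 difference of -0.21 ± 0.04 (adjusted p = 0.481). YSL12 differed by -0.34 ± 0.09 and ISAP1 by -0.34 ± 0.09, both with an adjusted p of 0.785. On the higher side were MT2B, a metallothionein, at 0.13 ± 0.04, the thioredoxin gene OsTrxh1 at 0.30 ± 0.11 and the tocopherol methyltransferase gene G-TMT at 0.17 ± 0.06, again with an adjusted p of 0.785. With limma, 0 of 34316 probe sets passed, against 2081 with an unadjusted p under 0.05, and the smallest adjusted p was 0.333. The live and dead arrays did not overlap for 4880 probe sets, 14.2% of those tested, where chance gives 10%. Leaving out replicate 1 of the dead group gave 26 calls.

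Among the 32 gene lists, 2 passed on day 1, both higher with live bacteria and both without any member past the threshold, also when adjusted over the list alone. In chlorophyll synthesis, 15 of 16 measured members were higher, with a median of 0.05 (camera, adjusted p = 0.00338; adjusted p = 0.745 with an estimated correlation). Its member with the smallest p was PORB, a protochlorophyllide reductase, at 0.13 ± 0.09. In the expansins, which loosen cell walls, 16 of 24 members were higher, with a median of 0.06 (adjusted p = 0.00836; adjusted p = 0.745 with an estimated correlation), and EXPA8 stood at 0.30 ± 0.14. The chlorophyll synthesis call was lost without replicate 3 of the dead group (adjusted p = 0.156) and without replicate 1 of the live group (adjusted p = 0.0768), and 1 list remained past the threshold without the former, against 5 without replicate 3 of the live group.

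On day 2 more probe sets passed than on any other day, although day 5 had more with array weights (16570 against 6722) and from its 2 groups alone (741 against 212). As lists, DNA replication, cell cycle and cytosolic ribosomal protein genes stood higher with live bacteria than other genes, and phenylpropanoid and lignin synthesis genes lower. Of their members 6 of 27, 3 of 21, 12 of 23 and 9 of 25 passed, and no list passed with an estimated correlation (adjusted p = 0.745). NIA1, a nitrate reductase gene (LOC4345795), fell by 1.03 on the log2 scale (SE 0.13), from 10.27 ± 0.13 with dead to 9.24 ± 0.06 with live bacteria (adjusted p = 0.000155). SWEET11, a sucrose transporter gene (LOC4346153), rose by 1.21 ± 0.23, from 8.66 ± 0.58 to 9.87 ± 0.16 (adjusted p = 0.00313). In all, 3814 probe sets passed, 1222 higher and 2592 lower.

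Besides SWEET11, the largest rises on day 2 among named genes whose live and dead arrays did not overlap belonged to RPA1B (1.09 ± 0.28) and RPA2A (0.92 ± 0.21), subunits of the single-strand binding replication protein A, and to OsTDL1B (0.99 ± 0.20). Next came OsMCM6 of the replicative helicase (0.94 ± 0.27), HATB (0.89 ± 0.21) and the kinesin genes KIN10B (0.82 ± 0.24) and DBS1 (0.80 ± 0.26). Under the same limit the largest falls were those of CBF3, a transcription factor of cold and dehydration responses (-1.55 ± 0.27), SAT1 (-1.21 ± 0.25) and NIA1. They were followed by MYB2 (-1.02 ± 0.25), the Aux/IAA repressor gene IAA6 (-0.98 ± 0.19), the urea transporter gene DUR3 (-0.97 ± 0.22) and the 4-coumarate-CoA ligase genes 4CL5 (-0.93 ± 0.17) and 4CL2 (-0.87 ± 0.11). DOF4 fell by 0.54 (SE 0.07, adjusted p = 0.000317). The fold change was at least 2 for 7 probe sets that rose and 60 that fell, and the median size among all called probe sets was 0.38 on the log2 scale. Of 2698 genes called, 401 carry a name and were open to naming here. Without regard to adjustment, 8690 probe sets had a p under 0.05, and live and dead arrays did not overlap for 8730 (25.4%, where chance gives 10%). The balance of directions rested on the scaling of the arrays: 32% of calls were higher here, 55.6% after quantile normalization and 38.2% after centring each array. The number of calls was 1226 without dead replicate 1, 1930 without dead replicate 2 and 2254 without live replicate 1. Of the 74 calls on genes named for this day, 45, 34 and 12 were lost without dead replicates 1, 2 and 3, and 26, 19 and 21 without live replicates 1, 2 and 3. The calls that held whichever array was left out included SWEET11, OsTDL1B, CBF3, SAT1, NIA1, IAA6, 4CL5, 4CL2 and DOF4. From the 2 groups alone SWEET11 (0.0618), SAT1 (0.0509), IAA6 (0.087) and 4CL5 (0.0614) were lost.

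**Figure D1:**
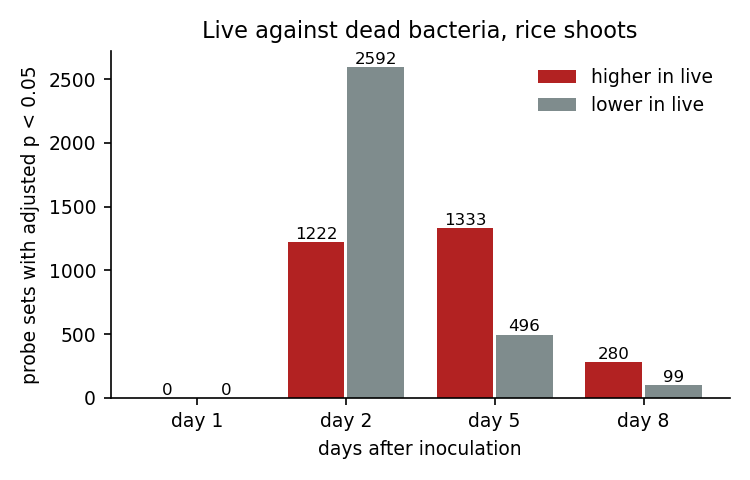
Number of probe sets with an adjusted p under 0.05 on each day after inoculation, with those higher in seedlings given live bacteria in red and those lower in grey (3 live and 3 dead arrays per day). The counts are 0 on day 1, 1222 higher and 2592 lower on day 2, 1333 higher and 496 lower on day 5, and 280 higher and 99 lower on day 8. After quantile normalization the higher share is 55.6% on day 2 and 50.1% on day 5.

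Grouped by the lists, 4 passed on day 2, and each of these held without any single array of the day. Of 10 splits of the arrays of that day, 5 gave as many lists, the real one included (highest other 8). Of 23 cytosolic ribosomal protein genes, 12 rose and 0 fell (19 and 1 adjusted over the list alone), with a median of 0.26 (camera, adjusted p = 1.45e-08; adjusted p = 0.745 with an estimated correlation). RPL11 rose by 0.49 ± 0.12, RPS4 by 0.48 ± 0.11 and RPS3A by 0.28 ± 0.06. Of 27 DNA replication genes, 6 rose and 0 fell (15 and 0 adjusted over the list alone), with a median of 0.42 (adjusted p = 4.01e-07; adjusted p = 0.745 with an estimated correlation). They included RPA1B, RPA2A and RPA14, the last at 0.38 ± 0.11. Of 21 cell cycle genes, 3 rose and 0 fell (10 and 0 adjusted over the list alone), with a list median of 0.41 (adjusted p = 0.00122; adjusted p = 0.745 with an estimated correlation). The 3 were the cyclins CYCD4-2 (0.76 ± 0.18), CYCB2 (0.62 ± 0.14) and CYCD2-2 (0.52 ± 0.14). Of 25 phenylpropanoid and lignin synthesis genes, 9 fell and 0 rose (12 and 1 adjusted over the list alone), with a median of -0.16 (adjusted p = 0.00715; adjusted p = 0.745 with an estimated correlation). Of the falls, 4CL2, 4CL5 and 4CL4 (-0.43 ± 0.07) held without any single array, but from the 2 groups alone 4CL5 (0.0614) and 4CL4 (0.0543) were lost. No named gene of the ribosomal, replication and cell cycle lists held its own call in every omission, and omitting dead replicate 1 lost 45 of the 74 named calls of the day.

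The remaining lists did not pass on day 2, although single members did. In the nitrogen list 2 of 15 fell, NIA1 and the ammonium transporter gene AMT1-1 (-0.64 ± 0.11). In the calcium and MAP kinase list 16 of 85 fell and 1 rose (22 and 2 adjusted over the list alone; list adjusted p = 0.0869), with falls of MPK3 (LOC4332475, -0.71 ± 0.13), CIPK19 (-0.39 ± 0.07) and CML1 (-0.36 ± 0.07). Heat shock genes went both ways, with 4 of 39 down, among them the heat shock factor genes HSFB1 (-0.71 ± 0.10, adjusted p = 0.000516) and HSFC1B (-0.59 ± 0.12) and HSP17.9B (-0.29 ± 0.05), and 2 up. In the sugar list 3 of 30 fell, including SWEET14 (-1.10 ± 0.33) and SWEET2B (-0.45 ± 0.12), and 2 rose. Hormone genes that passed were nearly all lower, but so were 2592 of the 3814 calls of the day. After quantile normalization 55.6% of the calls of the day were higher. For jasmonate 3 of 31 fell, OPR10 (-0.61 ± 0.17), AOS (-0.48 ± 0.14) and JAZ4 (-0.27 ± 0.08). For auxin 3 of 50 fell, IAA5 (-0.16 ± 0.04) and ARF2 (-0.25 ± 0.07) beside IAA6, and 1 other gene rose. For cytokinin 3 of 26 fell, LOGL5 (-0.37 ± 0.08), RR6 (-0.35 ± 0.10) and RR24 (-0.30 ± 0.09), and for gibberellin 2 of 16, CIGR1 (-0.55 ± 0.13) and CIGR2 (-0.42 ± 0.12). Single falls were seen in ethylene (EIL1A, -0.21 ± 0.05), brassinosteroid (CYP90A4, -0.42 ± 0.07) and abscisic acid (PYL11, -0.30 ± 0.05). The calls of NIA1, IAA6, AMT1-1, MPK3, CIPK19, CML1, HSFB1, HSFC1B, HSP17.9B, LOGL5, CYP90A4 and PYL11 held without any single array. From the 2 groups alone IAA6 (0.087), AMT1-1 (0.0614), MPK3 (0.0655), CIPK19 (0.0776), CML1 (0.0568), HSP17.9B (0.0618), LOGL5 (0.0839) and PYL11 (0.0678) were lost. The others were each lost without at least 1, and omitting dead replicate 1 lost 45 of the 74 named calls of the day.

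Symbiosis signalling had 2 of 8 genes up on day 2: CCAMK, the calcium- and calmodulin-dependent kinase of the common symbiosis pathway (0.37 ± 0.09, adjusted p = 0.0156), and CEBIP, a chitin receptor (0.47 ± 0.14). Expansins split into 4 up and 2 down of 24, with EXPA5 at 0.69 ± 0.19, EXPA7 at 0.66 ± 0.18 and EXLA1 at -0.61 ± 0.17. Among chlorophyll synthesis genes 2 of 16 rose, UROS (0.31 ± 0.08) and PORA (0.66 ± 0.20). In contrast, 2 of 13 members of the photosystem list fell, ndhM (-0.44 ± 0.13) and petC (-0.21 ± 0.07), as did 1 of 8 carbon fixation genes, GDCSH (-0.10 ± 0.03). The falls in phosphate genes (2 of 15) were SPX4 (-0.32 ± 0.07) and OsPht1;1 (-0.34 ± 0.10), and those in iron genes (3 of 20) were YSL12 (-0.32 ± 0.09), YSL6 (-0.39 ± 0.11) and 0sFRO1 (-0.42 ± 0.13). The iron list had a median of -0.10 and a mean of 0.06. CESA3 and CESA9 fell by 0.19 each among 13 cellulose synthesis genes, GSTZ3 by 0.30 among 6 glutathione S-transferases, and PRR95 by 0.27 and PRR73 by 0.15 among 7 clock genes, while OsCel9E rose by 0.54 among 9 xyloglucan and beta-glucan genes. No member passed among pathogenesis-related proteins (Cht11, 0.53 ± 0.27), diterpenoid phytoalexin genes (CYP71Z6, -0.37 ± 0.17), WRKY factors (WRKY51, -0.26 ± 0.10), histones (CenH3, 0.55 ± 0.19) or the root markers (Lsi1, -0.15 ± 0.10), and 1 of 8 seed markers fell (GLUA-2, -0.32 ± 0.07). SPX4 and PRR95 held without any single array but were lost from the 2 groups alone (0.0931 and 0.0922), PRR95 also after quantile normalization (0.0576), while the other calls in this group were each lost without at least 1, most often dead replicate 1, whose omission lost 45 of the 74 named calls of the day.

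On day 5, 72.9% of the calls were higher with live bacteria, but 50.1% after quantile normalization and 49.9% after centring. NIA1, which had been lower on day 2, rose by 0.77 ± 0.13, from 11.20 ± 0.33 with dead to 11.97 ± 0.12 with live bacteria (adjusted p = 0.00237). As lists, jasmonate and photosystem genes stood higher than other genes, and DNA replication and cell cycle genes lower. No list passed with an estimated correlation (adjusted p = 0.745), and the photosystem call was also lost after quantile normalization (0.161) and centring (0.251). The NAC transcription factor gene NAC067 rose by 0.94 ± 0.11 (adjusted p = 0.000158). In all, 1829 probe sets passed, 1333 higher and 496 lower. The axis that separates replicates within groups on the other days correlated, in size, at 0.451 with the day 5 differences across probe sets, against 0.373, 0.139 and 0.195 for days 1, 2 and 8.

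Among named genes whose live and dead arrays did not overlap, the largest rise on day 5 was that of EGY3 (LOC4333985), from 7.79 ± 0.17 to 9.12 ± 0.63 (1.33 ± 0.21, adjusted p = 0.00199). It was followed by the germin-like gene GER2 (1.05 ± 0.19), the jasmonate-responsive MYB gene JAMYB (1.01 ± 0.23), the beta-expansins EXPB2 (0.95 ± 0.17) and EXPB6 (0.92 ± 0.18) and NAC067. Then came the type-A cytokinin response regulator RR9 (0.92 ± 0.18) and the jasmonate repressor gene JAZ6 (0.85 ± 0.19). The largest falls under the same limit were smaller in size. They were BU1, a helix-loop-helix protein of brassinosteroid responses (-0.56 ± 0.14), CSLC9 (-0.56 ± 0.14), GLU8 (-0.55 ± 0.16), 4CLL7 (-0.53 ± 0.14), the Argonaute gene AGO17 (-0.50 ± 0.14), MOF1 (-0.46 ± 0.12), the tubulin gene pTUB22 (-0.41 ± 0.06) and KIN8B (-0.40 ± 0.10). The fold change was at least 2 for 21 probe sets that rose and 6 that fell, with a median size of 0.38 among the calls. Of 1099 genes called, 169 carry a name. An unadjusted p was under 0.05 for 8294 probe sets, and live and dead arrays did not overlap for 9609 (28%, where chance gives 10%). Centring each array gave 844 calls. The number of calls was 1001, 408, 712, 1209 and 1193 without dead replicate 1, dead replicate 2 and live replicates 1, 2 and 3. Of the 54 calls on genes named for this day, 18, 34 and 16 were lost without dead replicates 1, 2 and 3, and 28, 22 and 19 without live replicates 1, 2 and 3. The calls of EGY3, GER2, EXPB2, NAC067, EXPB6, RR9, JAZ6, pTUB22 and NIA1 held without any single array. From the 2 groups alone RR9 (0.0567) and JAZ6 (0.118) were lost.

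Of 31 jasmonate synthesis and signalling genes, 6 rose and 0 fell on day 5 (12 and 1 adjusted over the list alone), with a list median of 0.28 (camera, adjusted p = 0.00122; adjusted p = 0.745 with an estimated correlation). JAZ6, JAZ5 (0.83 ± 0.20) and the oxophytodienoate reductase gene OPR13 (0.28 ± 0.07) had the smallest p values. The list call was lost without live replicate 2 (adjusted p = 0.0751). Members of the photosystem list had a median of 0.09, with 2 of 13 up and 0 down (5 and 0 adjusted over the list alone), PSB28 (0.39 ± 0.09) and LFNR1 (0.17 ± 0.04). Their list passed at an adjusted p of 0.0366, with an adjusted p = 0.745 with an estimated correlation, 0.161 after quantile normalization and 0.251 after centring, and it was lost without dead replicates 2 (0.0763) and 3 (0.0823) and live replicates 1 (0.117) and 3 (0.0745). In DNA replication, 1 of 27 genes was above 0, the median was -0.22 and no member passed, also when adjusted over the list alone (adjusted p = 0.00122; adjusted p = 0.745 with an estimated correlation). POLD2 was nearest, at -0.53 ± 0.17. In the cell cycle list the median was -0.30 and 1 of 21 genes fell, KIN5A (-0.31 ± 0.09; adjusted p of the list 0.016; adjusted p = 0.745 with an estimated correlation). The cell cycle call was lost without dead replicate 1 (0.0502), without live replicate 3 (0.0741) and after quantile normalization (0.0788), and 2 lists remained past the threshold without live replicate 3.

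Members of other lists passed singly on day 5. Among nitrogen genes NIA1 and AMT1-1 (0.44 ± 0.11) rose and GLT2, a glutamate synthase gene, fell by 0.98 (SE 0.22), of 15 measured. Cytokinin genes had 3 up and 1 down of 26, with LOG, which activates cytokinins (0.62 ± 0.12), and RR4 (0.43 ± 0.11) beside RR9. The sugar transporter gene SWEET2B rose by 0.66 ± 0.12, the only call among 30 sugar and starch genes. In the calcium and MAP kinase list 5 of 85 rose and 2 fell, with MPK7 (0.67 ± 0.15), CML1 (0.34 ± 0.07) and MPK3 (LOC4328297, 0.31 ± 0.06). Expansins had 3 up and 0 down of 24, EXPB7 (0.43 ± 0.11) being the third. Rises were also called for RPL18 (0.47 ± 0.07) and RPL27 (0.21 ± 0.05) among 23 ribosomal genes, WRKY76 (0.72 ± 0.19) among 5 WRKY factors and the ethylene synthesis gene ACS1 (0.55 ± 0.14) among 10. Further rises were OsPht1;8 (0.53 ± 0.14) among 15 phosphate genes, HSFA2D (0.32 ± 0.09) and HSP16.0 (0.46 ± 0.13) among 39 heat shock genes. CAD1 (0.31 ± 0.09) rose among 25 phenylpropanoid genes, and PCL1 (0.42 ± 0.09) and PRR95 (0.27 ± 0.06) among 7 clock genes. Falls were called for ARF17 (-0.34 ± 0.08) and ARF16 (-0.29 ± 0.08) among 50 auxin genes and for BU1 and CYP90A4 (-0.26 ± 0.07) among 14 brassinosteroid genes. GLU2 rose (0.18 ± 0.04) and GLU8 fell in the xyloglucan and beta-glucan list. No member passed in the lists for carbon fixation (GLO5, 0.07 ± 0.04), chlorophyll synthesis (CPX, 0.21 ± 0.08), histones, cellulose synthesis (CESA5, -0.20 ± 0.06), or pathogenesis-related proteins (Cht11, 0.68 ± 0.27). The same held for diterpenoid phytoalexins, gibberellin, abscisic acid (ABA8OX1, -0.78 ± 0.25), iron, glutathione S-transferases, symbiosis signalling (CCAMK, -0.26 ± 0.09, adjusted p = 0.1), seed markers and root markers. RPL18, LOG, NIA1, RR9, SWEET2B, MPK3 and CML1 held without any single array. LOG (0.0989) and RR9 (0.0567) were lost from the 2 groups alone, and MPK3 (0.0582) and CML1 (0.0858) after centring. The other calls here were each lost without at least 1, most often dead replicate 2, whose omission lost 34 of the 54 named calls of the day.

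**Figure D2:**
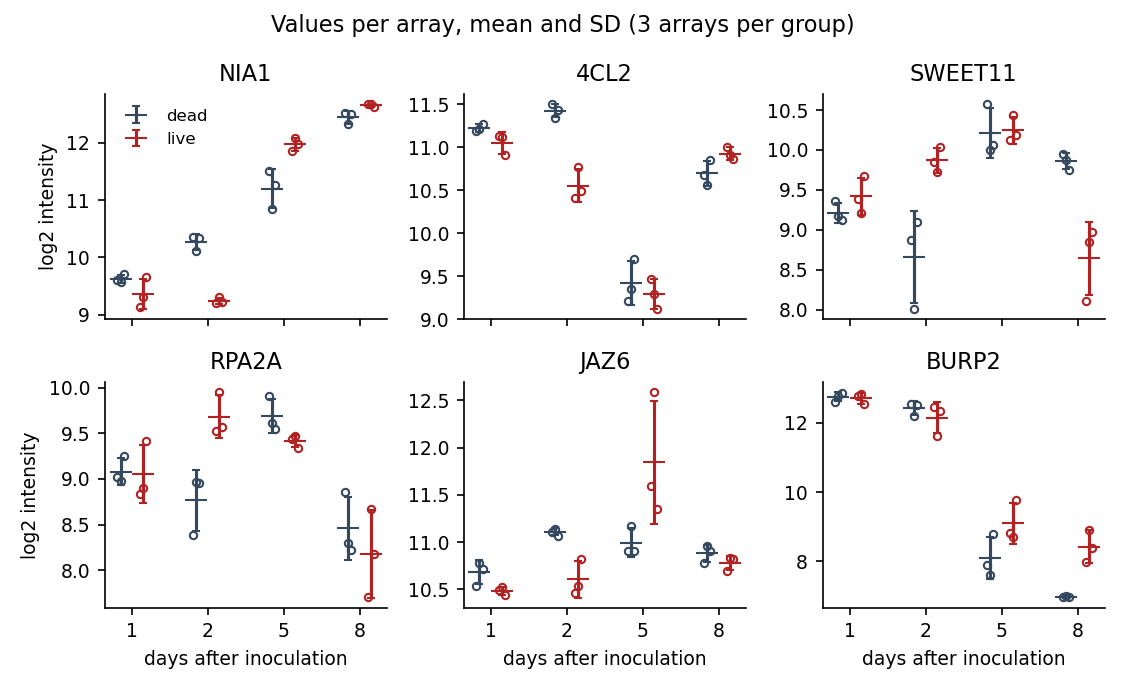
Log2 intensity of 6 genes in each array (points) with the group mean and SD (bars), for seedlings given dead (blue) and live (red) bacteria 1, 2, 5 and 8 days after inoculation, 3 arrays per group. NIA1 was lower with live bacteria on day 2 (-1.03) and higher on day 5 (0.77). 4CL2 (-0.87) and RPA2A (0.92) differed on day 2, JAZ6 (0.85) on day 5 and BURP2 on days 5 (1.00) and 8 (1.45). SWEET11 was higher on day 2 (1.21) and lower on day 8 (-1.22).

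On day 8 fewer genes passed, and most were higher with live bacteria. BURP2 (LOC4338119) rose by 1.45 ± 0.28, from 6.98 ± 0.02 with dead to 8.43 ± 0.47 with live bacteria (adjusted p = 0.0142), and the aquaporin gene OsPIP2;7 (LOC4347729) by 0.39 ± 0.06 to 12.39 ± 0.06 (adjusted p = 0.00406). SWEET11 fell by 1.22 (SE 0.23), from 9.86 ± 0.10 to 8.64 ± 0.46 (adjusted p = 0.0117). Ribosomal protein, chlorophyll synthesis and photosystem genes stood slightly higher than other genes, and clock, cell cycle and DNA replication genes slightly lower; no list passed with an estimated correlation (adjusted p = 0.745). In all, 379 probe sets passed, 280 higher and 99 lower, against 38 from the 2 groups alone, 235 without the trend, 580 after quantile normalization and 2165 with array weights. Further rises were those of CLA1, the deoxyxylulose phosphate synthase of plastid isoprenoid synthesis (0.55 ± 0.11), KPHMT1 (0.53 ± 0.11), CIPK29 (0.51 ± 0.11), P1/P2-like (0.43 ± 0.10), LPR2 (0.42 ± 0.10) and the peroxiredoxin gene PRXIIE-2 (0.42 ± 0.07). Further falls were those of OsTDL1B (-0.88 ± 0.20), the germin-like gene GER4 (-0.70 ± 0.13), OsRac2 (-0.68 ± 0.15), the cyclin CYCP4-1 (-0.61 ± 0.13), mfs1 (-0.54 ± 0.10), the phosphatase gene OsPP2C33 (-0.51 ± 0.10) and AtbHLH004 (-0.47 ± 0.10). Of 275 genes called, 48 carry a name; 5 probe sets rose and 5 fell by a fold of at least 2, and the median size was 0.41. An unadjusted p was under 0.05 for 4260 probe sets, and live and dead arrays did not overlap for 7180 (20.9%, where chance gives 10%). The number of calls was 208, 22, 21 and 250 without dead replicate 1, dead replicate 2, live replicate 1 and live replicate 3. Of the 30 calls on genes named for this day, 18, 27 and 12 were lost without dead replicates 1, 2 and 3 and 28, 8 and 16 without live replicates 1, 2 and 3, and only that of OsPIP2;7 held in each omission. From the 2 groups alone its adjusted p was 0.0521, and 0 of the 30 calls held in every alternative.

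Gene lists on day 8 showed small shifts over many members. Of 23 cytosolic ribosomal protein genes 22 were above 0, with a median of 0.16, and 1 rose, RPL27 at 0.24 ± 0.04 (6 adjusted over the list alone, 0 down; camera, adjusted p = 4.01e-07; adjusted p = 0.745 with an estimated correlation). Of 16 chlorophyll synthesis genes 15 were above 0, with a median of 0.21, and 1 rose, the coproporphyrinogen oxidase gene CPX at 0.36 ± 0.08 (8 adjusted over the list alone, 0 down; adjusted p = 1.06e-05; adjusted p = 0.745 with an estimated correlation). The photosystem list had a median of 0.06 and 1 rise of 13, OEE3 of the oxygen-evolving complex at 0.20 ± 0.04 (3 adjusted over the list alone, 0 down). Its camera adjusted p was 0.00584, and 0.745 with an estimated correlation. All 7 clock genes were below 0, with a median of -0.13 and no member past the threshold over all probe sets (3 down adjusted over the list alone; adjusted p = 0.0141; adjusted p = 0.745 with an estimated correlation), GI being nearest at -0.17 ± 0.04. The clock call was lost without dead replicate 2 (0.134), live replicate 2 (0.0509) and live replicate 3 (0.064). The cell cycle list had a median of -0.24 and no call (1 down adjusted over the list alone; CYCD2-2, -0.51 ± 0.14; adjusted p = 0.0166; adjusted p = 0.745 with an estimated correlation). It was lost without dead replicate 1 (0.284) or live replicate 1 (0.4). The DNA replication list had a median of -0.20 and no call, also when adjusted over the list alone (RFC1, -0.15 ± 0.07; adjusted p = 0.0169; adjusted p = 0.745 with an estimated correlation). It was lost without dead replicate 1 (0.429), live replicate 1 (0.411) or live replicate 3 (0.0537). In lists that did not pass, CML1 (0.37 ± 0.07), CIPK7 (0.30 ± 0.06) and CIPK29 rose among 85 calcium and MAP kinase genes and GDCSH (0.16 ± 0.03) among 8 carbon fixation genes. The auxin repressor gene IAA30 (-0.40 ± 0.09), the brassinosteroid kinase gene GSK2 (-0.38 ± 0.09), the glucanase gene GLU1 (-0.36 ± 0.09) and SWEET11 fell. Every other list had 0 members past the threshold, symbiosis signalling (CERK1, -0.12 ± 0.07), jasmonate (JAZ3, -0.24 ± 0.10), nitrogen (AMT2-1, 0.40 ± 0.19), pathogenesis-related proteins (Cht10, 0.28 ± 0.12) and the seed and root markers among them. Each single-gene call named here was lost without at least 1 array, most often live replicate 1, whose omission lost 28 of the 30 named calls of the day.

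**Figure D3:**
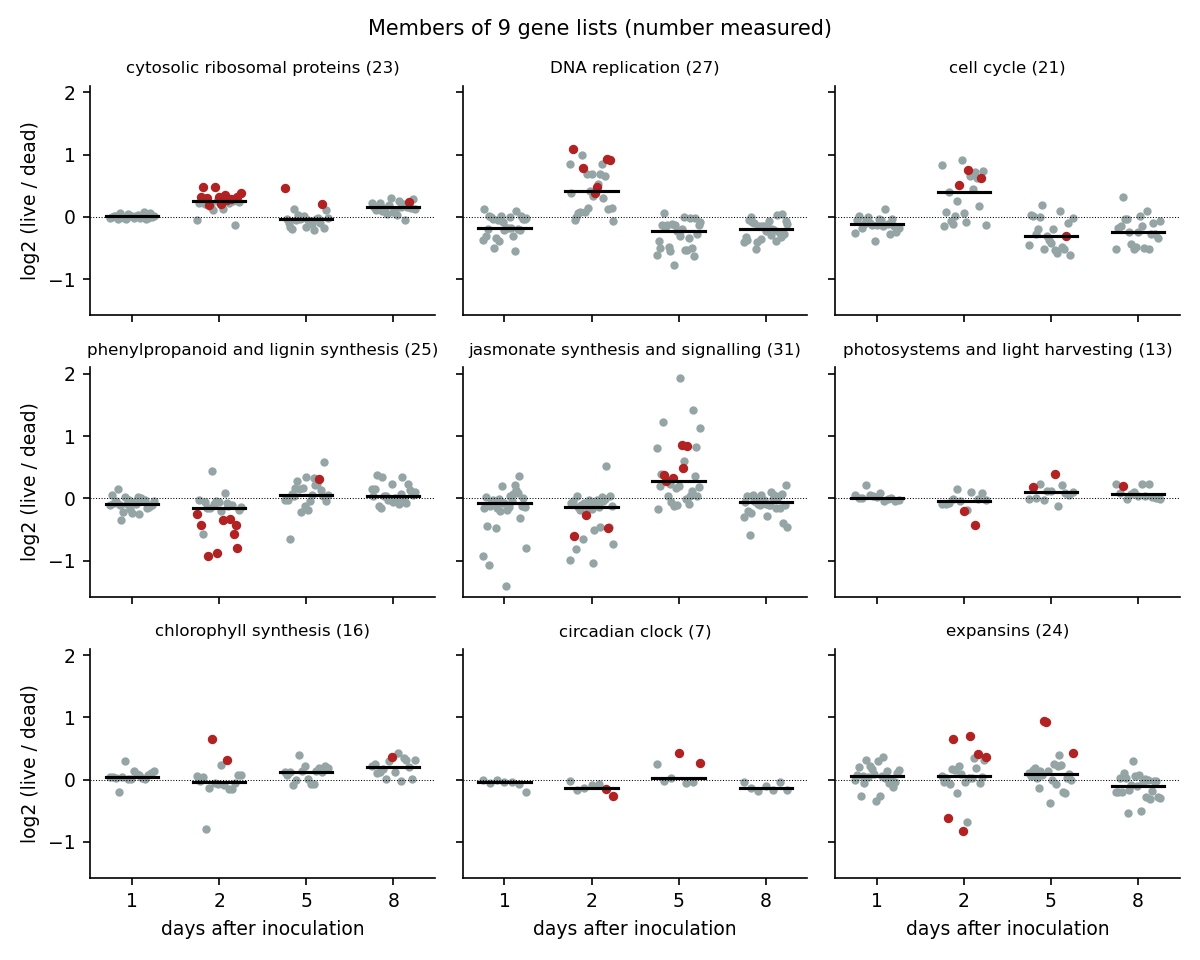
Log2 difference between live and dead bacteria of each measured member of 9 gene lists on days 1, 2, 5 and 8; red points passed the threshold over all probe sets, grey points did not, and bars are medians. Medians of DNA replication and cell cycle genes were 0.42 and 0.41 on day 2 and -0.22 and -0.30 on day 5, and the jasmonate median was 0.28 on day 5.

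Whether the response itself differed between the days was tested directly. NIA1 was at -0.26 ± 0.13 on day 1, fell by 1.03 on day 2, rose by 0.77 on day 5 and stood at 0.21 ± 0.13 on day 8 (adjusted p of the difference between days 9.25e-05). NAC067 went from a fall of 0.47 (log2, -0.47 ± 0.11) on day 2 to a rise of 0.94 ± 0.11 on day 5 (0.000186) and the aquaporin gene OsPIP1;3 from -0.36 ± 0.08 to 0.61 ± 0.08 (0.000278). The peroxisome proliferation gene OsPEX11-4 went from -0.35 ± 0.07 to 0.47 ± 0.07 (0.000366) and the calmodulin-like gene CML1 from -0.36 ± 0.07 to 0.34 ± 0.07, with 0.37 ± 0.07 on day 8 (0.000551). DOF4 fell by 0.54 on day 2 and stood at 0.20 ± 0.07 on day 5 (0.000551). SWEET11 and OsTDL1B, which rose on day 2 and fell on day 8, had adjusted p values of 0.000951 and 0.00207. Across all genes 3743 probe sets differed in response between days (9084 with an unadjusted p under 0.05), and 2190 without replicate 1 of dead day 2. Between pairs of days, 6003 probe sets differed from day 2 to day 5 (3804 more positive on day 5, 2199 more negative) and 3387 from day 2 to day 8 (2223 and 1164). There were 115 from day 5 to day 8 (16 and 99), 72 from day 1 to day 5 (68 and 4) and 9 from day 1 to day 2, all more negative on day 2. From day 1 to day 8 limma called 0, with 2728 at an unadjusted p under 0.05.

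Calls of day 2 and day 5 overlapped mostly with opposite sign. Lower on day 2 and higher on day 5 were 355 probe sets, where independent lists would share 101 (Fisher's exact test, 1.31e-104), and higher on day 2 and lower on day 5 were 72, against 17.7 (3.32e-24); probe sets are not independent replicates. After quantile normalization these counts were 143 and 221, and without the filter on dim probe sets 221 and 40. In the same direction, 7 were higher and 17 lower on both days, against 47.5 and 37.5. Day 2 and day 8 shared 121 that were lower and then higher, against 21.2 (6.5e-61), and 38 that were higher and then lower, against 3.53 (2.27e-29), with 66 after quantile normalization and 20 without the filter. Day 5 and day 8 shared 70 that were higher on both, against 10.9 (1.66e-36; 41 without the filter), and 5 that were lower, against 1.43 (0.0146; 24 after quantile normalization). Across tested probe sets the differences of day 2 correlated at -0.279 with those of day 5 and at -0.324 with those of day 8, and those of day 5 at 0.212 with those of day 8. Of 100 regroupings of the arrays within days 2 and 5, 15 gave a correlation as large in size. The days share no arrays, but their calls share 1 estimate of spread per probe set. Called lists of different days are therefore not independent. Genes in the same direction on 2 days included BURP2 (1.00 ± 0.28 on day 5, 1.45 ± 0.28 on day 8), CML1, the plastid isoprenoid gene ISPF (0.47 ± 0.08 and 0.37 ± 0.08) and CEST (0.33 ± 0.06 and 0.30 ± 0.06), all on days 5 and 8. On the same 2 days they were the ribosomal protein gene rpl5 (0.30 ± 0.09 and 0.36 ± 0.09), the thioredoxin gene OsTrxy (0.26 ± 0.07 and 0.31 ± 0.07) and the glutaredoxin gene GRXS7 (0.21 ± 0.05 and 0.22 ± 0.05). On days 2 and 5 they were GER1 (0.59 ± 0.19 and 0.64 ± 0.19), EXPB7 (0.36 ± 0.11 and 0.43 ± 0.11) and CYP90A4 (-0.42 ± 0.07 and -0.26 ± 0.07). Of these calls only those of ISPF and CML1 on day 5 and CYP90A4 on day 2 held without each single array. Those of GER1 were lost in 5 of 6 omissions on each day and that of BURP2 on day 5 in 4 of 6. There were 102 such probe sets, 79 higher and 23 lower, and 0 in the same direction on 3 days.

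An effect common to all days, the mean of the differences on the 4 days, was called for 26 probe sets that were higher and 99 that were lower (6030 with an unadjusted p under 0.05). The higher share was 20.8% here, 38.1% after quantile normalization and 7.37% after centring. The total was 392 and 409 with the replicate number as a block within days and over all days, 427 with a filter at the 60th percentile, 40 without the trend and 4627 with array weights. With same-numbered arrays kept apart on every day, 9 of 100 splits gave as many calls. Single arrays moved this count widely. It was 1139 without live day 2 replicate 2; 364, 28 and 47 without dead day 1 replicates 1, 2 and 3; 28 without live day 1 replicate 1; 42 and 81 without dead day 2 replicates 1 and 2; and 32 without live day 2 replicate 1. It was 289, 27 and 63 without dead day 5 replicates 1, 2 and 3, and 34 and 246 without live day 5 replicates 1 and 2. It was 30 and 37 without dead day 8 replicates 2 and 3, and 40, 51 and 36 without live day 8 replicates 1, 2 and 3.

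The seedlings given dead bacteria show how the shoot changed with age, the background for the comparisons between inocula. From day 1 to day 8, 2 clock genes were among the largest changes of named genes. The morning gene CCA1 (LOC4344703) rose by 6.39 ± 0.12 and the evening gene PCL1 (LOC4326391) fell by 6.89 (SE 0.09). On days 1, 2, 5 and 8 the control means of CCA1 were 6.88, 6.91, 11.09 and 13.27, and those of PCL1 were 13.07, 13.24, 8.13 and 6.18, while live and dead seedlings of the same day differed in CCA1 by 0.00, -0.03, 0.25 and -0.04 and in PCL1 by -0.03, -0.09, 0.42 (adjusted p = 0.0138) and -0.11. Every other change given here for day 1 to day 8 lies between days whose clock genes differed in this way. Besides CCA1, the largest rises among named genes whose arrays of the 2 days did not overlap were those of HSP18.6 (5.18 ± 0.16), SWEET2B (4.73 ± 0.12), the ferric reductase gene 0sFRO1 (4.34 ± 0.13), AMT1-1 (4.08 ± 0.11) and the starch synthase gene SSI (3.64 ± 0.25). Under the same limit the largest falls were those of the nicotianamine synthase genes NAS1 (-6.90 ± 1.28) and NAS2 (-5.50 ± 1.04), PCL1, the proteinase inhibitor gene RBBI3.3 (-6.79 ± 0.42), BURP2 (-5.77 ± 0.28) and PM19L (-5.47 ± 1.04). In all, 20089 probe sets passed from day 1 to day 8 (9582 higher, 10507 lower), with a fold of at least 2 for 2007 and 3574. Of 11226 genes called, 1577 carry a name.

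**Figure D4:**
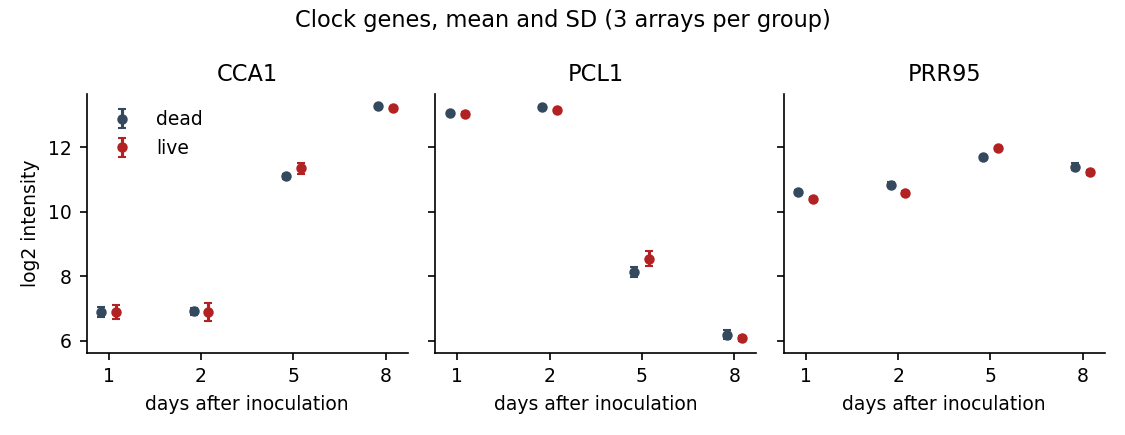
Mean log2 intensity and SD of the clock genes CCA1, PCL1 and PRR95 in shoots given dead (blue) and live (red) bacteria 1, 2, 5 and 8 days after inoculation, 3 arrays per group. Control CCA1 was 6.88 on day 1 and 13.27 on day 8, and control PCL1 was 13.07 and 6.18. Live and dead seedlings differed on day 5 by 0.42 in PCL1 and 0.27 in PRR95, on day 2 by -0.27 in PRR95, and in CCA1 by at most 0.25.

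Of the 32 lists, 4 passed in the control from day 1 to day 8, in the same direction under quantile normalization and centring and without each single array. All 23 ribosomal protein genes fell (23 adjusted over the list alone), with a median of -1.10, among them RPL18 (-1.21 ± 0.07) and RPL27 (-0.93 ± 0.04; camera, adjusted p = 1.78e-08; adjusted p = 0.806 with an estimated correlation). In the calcium and MAP kinase list 45 of 85 rose and 14 fell, the same numbers adjusted over the list alone (adjusted p = 0.0158; adjusted p = 0.806 with an estimated correlation). The members with the smallest p nevertheless fell, CIPK10 (-2.50 ± 0.09) and CIPK7 (-2.15 ± 0.06), the latter with a second probe set called in the opposite direction (0.61). Cellulose synthesis genes had 10 up and 1 down of 13, also when adjusted over the list alone, with CESA8 (0.56 ± 0.06) and CESA3 (0.54 ± 0.05; adjusted p = 0.0277; adjusted p = 0.806 with an estimated correlation). Auxin genes had 25 up and 7 down of 50 (26 and 8 adjusted over the list alone), with PIN5A, of the auxin efflux carriers, at 2.82 ± 0.12 and ARF23 at 1.83 ± 0.10 (adjusted p = 0.0277; adjusted p = 0.806 with an estimated correlation). Chlorophyll synthesis genes had 10 down and 5 up of 16, with CHLD (-1.86 ± 0.08) and CPX (-1.85 ± 0.08), and did not pass as a list (adjusted p = 0.213). Other changes in lists that did not pass included the glutamate synthase gene GLT2, which fell by at least 5.43 because all 3 day 8 arrays were at the floor, HSFC1B (-3.75 ± 0.12), CAD8C (-3.41 ± 0.12) and CAD3 (2.09 ± 0.09). Also changed were the ethylene synthesis gene ACO1 (-3.01 ± 0.17), SUS4 (-2.79 ± 0.16), OsPht1;4 (3.60 ± 0.25) and GSTF1 (2.99 ± 0.15). Further changes were those of PHO1-2 (2.97 ± 0.17), PSAG of photosystem I (2.67 ± 0.12), EXPB7 (2.17 ± 0.11), ZEP (1.93 ± 0.07), HK5 (1.56 ± 0.07), RR6 (-1.72 ± 0.10), CCAMK (-1.14 ± 0.09) and COI1 (1.09 ± 0.06). Seed markers had 2 up and 2 down of 8, with AMY1.5 at 1.94 ± 0.18, and root markers 1 up and 3 down of 5, with Lsi1 at -0.60 ± 0.10.

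Between neighbouring days of the control, 9369 probe sets changed from day 1 to day 2 (4796 higher, 4573 lower; 461 with a fold of at least 2). There were 22551 from day 2 to day 5 (9276 higher, 13275 lower; 3786) and 18935 from day 5 to day 8 (10079 higher, 8856 lower; 2553). From day 2 to day 5 the median of all tested probe sets shifted by -0.115 on the log2 scale as the values were given, and that shift is part of every change between these days. The higher share of calls was 51.2% from day 1 to day 2, against 37.2% after centring, 41.1% from day 2 to day 5, against 51.7% after quantile normalization and 57.6% after centring, and 53.2% from day 5 to day 8, against 37.1% after centring. Without replicate 2 of dead day 2, 6147 probe sets changed from day 1 to day 2. The clock gene CCA1 changed by 0.03 between the control means of days 1 and 2, the days with the fewest calls. On both days CCA1 was near its lowest control mean, where it says little about the clock. Every other gene of the clock list rose by more, PRR37 from 10.38 to 10.78 and PRR95 from 10.60 to 10.84 among them.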

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

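The test of CCA1 and PCL1 within day 2 and the splits that keep same-numbered arrays apart were chosen only after the results were seen. The response to live bacteria was not equal on the 4 days for 3743 probe sets, a difference between days tested directly. Between pairs of days, 9 probe sets differed from day 1 to day 2, 72 from day 1 to day 5, 6003 from day 2 to day 5, 3387 from day 2 to day 8 and 115 from day 5 to day 8. For single genes, the adjusted p of the difference between days was 9.25e-05 for NIA1, 0.000186 for NAC067, 0.000278 for OsPIP1;3, 0.000366 for OsPEX11-4 and 0.000551 for both DOF4 and CML1. Among 100 splits of the arrays made within each day, the real one alone reached 3743 (1 of 100, highest other 2164). The splits stand for no difference between live and dead on any day, and only against that is chance excluded at the 0.05 level. They cannot test whether an equal difference on all days would give this number. These splits ignore replicate numbers; with same-numbered live and dead arrays kept apart it was 1 of 100 for pairs on day 1 (highest other 1685) and 2 of 100 for pairs on every day (highest other 3910).

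Genes with a lower value on day 2 tended to have a higher one on day 5, NIA1, NAC067 and CML1 among them, with a correlation of -0.279 across probe sets. Scaling of the arrays alone is argued against, because the correlation was -0.283 after quantile normalization. Chance is not excluded: 15 of 100 combinations of splits of the day 2 and day 5 arrays gave a correlation as large in size, up to 0.532. A shared axis along which replicates of one group differ also stays open, because with the main axis of the day 1 and day 8 replicates removed the correlation was -0.121, between the bounds set for that test. A change of the response between these days is the explanation the design names; 6003 probe sets differed directly between them, which does not settle what sets the correlation.

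Day 2 had the most called probe sets in the fit used here, though not with array weights (6722 against 16570 on day 5). The array farthest from its group, live replicate 3, is argued against as the source of the whole count, since 3266 probe sets were called without it, but only 2467 of them were among the 3814. The axis that separates replicates on the other days may contribute: its correlation with the day 2 differences was 0.139, under the bound of 0.2 set beforehand, but the range without single arrays was 0.0594 to 0.263 and crosses that bound, so this explanation stays open. A different hour of harvest for live and dead seedlings also stays open; CCA1 differed by -0.028 on day 2, but it sat there within 0.5 of its lowest group mean and PCL1 within 0.5 of its highest, where the test is insensitive. An effect of live bacteria is the explanation the design names, and these tests do not separate it from the open ones.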

How the results depend on the processing

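The settings that leave out the array farthest from its group, and centring for gene lists, were chosen after the results were seen. The majority of calls turned with the scaling: on day 2 from 32% higher to 55.6% after quantile normalization, and in the control from 51.2 to 37.2% (days 1 to 2), 41.1 to 57.6% (days 2 to 5) and 53.2 to 37.1% (days 5 to 8) after centring. From control day 1 to day 8 it turned from 47.7 to 53.8% after quantile normalization. Totals not named here stayed within 1.5 times their main value, but counts by direction moved further. Among these, day 2 higher (main 1222) was 729 with the replicate block within days and 759 without a filter, and day 5 lower (main 496) was 248 with that block and 796 with a floor of 64. The cause of the moves below was not tested, except that fits on only 2 groups and fits without an array use fewer samples. Day 1 (main 0) gave 3 without a filter, 1481 with array weights and 4 with a floor of 64. Day 2 gave 2372 after centring, 6722 with weights and 212 from its 2 groups alone. Day 5 gave 844, 16570 and 741 in the same order. Day 8 gave 580 after quantile normalization, 235 without the trend, 2165 with weights and 38 from its 2 groups. The mean over days gave 427 at the 60th percentile, 40 without the trend, 4627 with weights, 203 without probe sets that match several transcripts and 324 with a floor of 64. The difference between days gave 2282 after centring and 17419 with weights. With an estimated correlation 0 lists passed on each of the 4 days. Fry called 1, 11 and 2 on days 1, 2 and 8, quantile normalization 2 on day 5, and 8 passed on day 2 without the far array. Fry ended both list calls of day 1 (adjusted p = 0.615 for chlorophyll synthesis and 0.522 for expansins). It also ended those of DNA replication and cell cycle on days 2 (0.0524 and 0.135), 5 (0.147 and 0.196) and 8 (0.295 and 0.235). On day 8 chlorophyll synthesis (0.0641) and ribosomal proteins (0.135) were lost too.

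With the replicate number as a block within days, 0, 3076, 1359 and 335 probe sets were called on days 1, 2, 5 and 8, and 392 for the mean over days (409 with 1 block over all days). Of the list calls, the block ended only that of photosystems on day 5 (adjusted p = 0.0509). Same-numbered live and dead arrays correlated at -0.328, 0.122 and -0.0378 on day 5 and at -0.228, -0.305 and 0.139 on day 8. By this check the numbers are shared labels on those days. On day 2 they correlated at 0.0317, 0.465 and 0.333. Of these, 2 are above 0.1 and larger than any day 1 value, so pairing stays open on both days. On days 1 and 2 each array correlated best with its own number, a hint from the data. The block within days was not run for the control changes, which it makes inestimable.

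Shared calls moved for days 2 and 5 (higher on both 3 and lower on both 8 without a filter; higher then lower 221 after quantile normalization and 40 without a filter; lower then higher 143 and 221). They also moved for days 2 and 8 (after quantile normalization 5 higher and 2 lower on both, and 66 higher then lower, 20 without a filter) and days 5 and 8 (higher on both 41 without a filter; after quantile normalization 24 lower on both, 1 higher then lower and 2 lower then higher, 0 of these without a filter).

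Leaving out single arrays gave counts of 0 to 26 on day 1, 1226 to 3454 on day 2, 408 to 1528 on day 5, 21 to 293 on day 8, 27 to 1139 for the mean over days, 2190 to 4478 for the difference between days and 6147 to 8799 for control days 1 to 2. The lists numbered 1 to 5, 4 to 8 and 2 to 4 on days 1, 2 and 5. Of the named live against dead calls, 24 of 74 on day 2, 17 of 54 on day 5 and 1 of 30 on day 8 held without each array, as did 67 of 69 in the control. Only 8, 12 and 0 of them, and 66 in the control, held in every alternative. Dim probe sets near the floor limit what could be called.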

Other observations

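The families in this and the next paragraph were chosen by gene name only after the results were seen, and so were the test of CCA1 and PCL1 between control days, the splits for the replicate axis and the splits that keep same-numbered arrays apart. The families were tested on those same results, so their p values and the calls that held are no independent support. Kinesins are the motor proteins of microtubules, and members were taken by gene name alone. Of 34 measured, 2 of them also in the cell cycle list, 9 rose and 1 fell on day 2, with a median of 0.28 (camera adjusted over 6 families and 4 days, p = 1.39e-05; adjusted p = 0.34 with an estimated correlation). KIN14N rose by 0.73 ± 0.20, KIN12E by 0.68 ± 0.18, KCH1 by 0.61 ± 0.17 and KIN13B by 0.30 ± 0.06, while KIN14O fell by 0.51 (SE 0.15). On day 5, 3 kinesins fell and 0 rose, KIN8B, KIN14C (-0.32 ± 0.09) and KIN5A, with a median of -0.28 (1.57e-05; adjusted p = 0.34 with an estimated correlation). On day 8 the median was -0.21 with 0 members past the threshold (3.55e-05; adjusted p = 0.34 with an estimated correlation). These directions were the same after quantile normalization and centring, and the 3 family calls held without each single array. The day 8 median was -0.11 without live replicate 1 (camera, adjusted p = 0.00749).

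Plastid isoprenoid synthesis feeds carotenoids and the chlorophyll side chain. Of 10 of its genes measured, 3 rose on day 5, OsPSY2 of carotenoid synthesis (0.53 ± 0.08), ISPF (0.47 ± 0.08) and ISPG (0.26 ± 0.06), with a family median of 0.23 (adjusted p = 0.000189; adjusted p = 0.167 with an estimated correlation). On day 8 ISPF and CLA1 rose and the median was 0.05 (adjusted p = 0.0491; adjusted p = 0.34 with an estimated correlation). The day 8 call was lost without dead replicate 1 (0.0684), dead replicate 3 (0.0912) or live replicate 1 (0.271). On day 1 the family also stood higher, with a median of 0.06 (0.0183; adjusted p = 0.34 with an estimated correlation), lost without dead replicate 3 (0.284) or live replicate 1 (0.11). Of 6 NAC genes, 2 fell on day 2 and 2 rose on day 5 (0.0491 on day 5; adjusted p = 0.34 with an estimated correlation), lost without dead replicate 3 (0.0976) or live replicate 2 (0.103). Of 8 germin-like genes 1 rose on day 2, 2 rose on day 5 and 1 fell on day 8, and the family passed on day 1 (0.00969; adjusted p = 0.34 with an estimated correlation) with 0 members past the threshold. Of 10 SWEET genes 1 rose and 3 fell on day 2, 1 rose on day 5 and 1 fell on day 8. Of 19 aquaporins 1 rose and 2 fell on day 2, 1 rose on day 5, and 1 rose and 1 fell on day 8. Neither family passed on any day.

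In the control, CCA1 rose by 6.39 on the log2 scale from day 1 to day 8 and PCL1 fell by 6.89. Scaling of the arrays is argued against, since PCL1 still changed by -6.82 after quantile normalization. A different hour of harvest on different days stays open. CCA1 (6.39) and PCL1 were chosen for their change, so their size alone cannot decide it. All 7 genes of the clock list changed from day 1 to day 8 (3 up and 4 down), but so did 58.5% of all tested probe sets. These values do not tell the hour of harvest from age. The hour of collection is not given in the sources used here, and a change of the clock with seedling age was not tested. If the hour did differ, control changes between days may mix age with time of day, whereas live and dead seedlings of one day differed by at most 0.25 in CCA1, and in PCL1 by 0.42 on day 5 (adjusted p = 0.0138).

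Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. For calls on day 1, 10 of 10 splits gave as many as the real one (0, highest other 2). On that day the numbers may pair the samples. The 3 other splits that part each same-numbered pair gave 0 calls each and 3, 1 and 1 lists. The 6 that do not gave up to 2 calls and 6 lists. On days 2, 5 and 8 the real split alone gave its count (1 of 10; 3814, 1829 and 379, highest other 949, 189 and 243). In the control the real split alone gave 9369, 22551, 18935 and 20089 calls for the steps from day 1 to 2, 2 to 5, 5 to 8 and 1 to 8, with 0 in every other split (1 of 10 each). For gene lists, as many passed in 8 splits on day 1 (real 2, highest other 6), 5 on day 2 (4 and 8), 3 on day 5 (4 and 4) and 2 on day 8 (6 and 6). For the mean over days, 3 of 100 splits made within days, the real one included, gave as many calls as the real one (26 higher and 99 lower). The highest other gave 425, and what sets such high counts was not tested. With same-numbered live and dead arrays kept apart it was 2 of 100 for pairs on day 1 (highest other 597) but 9 of 100 for pairs on every day (highest other 3105), so chance is not excluded there for this count. The axis that separates replicates on the other days correlated, in size, with the differences of days 1, 2, 5 and 8 at 0.373, 0.139, 0.451 and 0.195. As large a value came from 4, 6, 1 and 8 of 10 splits (highest other 0.548, 0.537, 0.407 and 0.344), so the axis lay closest to the differences of day 5. Without single arrays the day 5 value ranged from 0.399 to 0.574, so a part of this axis in the day 5 calls stays open.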
